A study of Mus musculus with 52 samples.

How the data were processed

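Hippocampal RNA from 4-month-old mice was measured by RNA sequencing in 52 libraries of 4 groups. The labels call the groups T2CV Ctl, T2CV SD, 5xFAD/T2CV Ctl and 5xFAD/T2CV SD. 5xFAD is a transgenic mouse model of Alzheimer's disease that carries human transgenes, mutant APP among them, under the neuronal Thy1 promoter. Ctl is taken as the control condition. SD is taken as sleep deprivation because the series title speaks of sleep; the labels do not spell it out. T2CV is not expanded in the sources used here and is kept as written. Per the labels' protocols, RNA was taken up in TRIzol and cleaned on columns, and 1 ug of total RNA went into a low-input SMARTer library. The series text speaks of triplicates of 5xFAD and wild-type mice, which differs from the group sizes given by the sample labels; the sample labels were used.

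The authors deposited 1 table per library with gene counts, CPM and FPKM. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, aligned to GRCm38 with STAR 2.7.9a and counted with featureCounts 2.0.3 of the Subread package. The deposited counts are whole numbers of assigned reads per gene. The deposited CPM are the counts scaled to a fixed total of assigned reads per library, and recomputing them gave a largest difference of 2.3e-10. The deposited FPKM are those CPM divided by gene length in kilobases, with a largest difference of 1.3e-10. Only the counts entered tests. The annotation release and the strandedness of the libraries are not given in the sources used here, so reads of overlapping genes on opposite strands, such as Tsix and Xist, could not be told apart. Each table held 55487 features, of which 55141 carried a gene symbol and 346 did not. No pair of tables was identical.

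Assigned counts per library, given in M (mega-counts), had a median of 47.2 M. They ran from 29.3 to 65.7 M in 5xFAD/T2CV Ctl, from 39.3 to 73.1 M in T2CV Ctl and from 35.7 to 67.3 M in T2CV SD. In 5xFAD/T2CV SD they ran from 1.78 to 52.2 M, with a median of 44.1 M. The lowest value belonged to the library labelled 5xFAD/T2CV SD replicate 6, and the next lowest of all 52 was 29.3 M. Counts of reads are not counts of independent molecules, so depth describes counting error only.

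The sample titles carry a number per mouse. In T2CV SD, 3 pairs of libraries share such a number and their counts were summed, which gave 49 mice: 13 T2CV Ctl (6 female, 7 male), 17 T2CV SD (5 female, 12 male), 12 5xFAD/T2CV Ctl (6 female, 6 male) and 7 5xFAD/T2CV SD (5 female, 2 male). That 1 number stands for 1 mouse is not stated by the labels, and p-values measure the spread between these samples. The numbers fall into bands under 300, from 300 to under 900, and of 900 and over, which were taken as possible cohorts. T2CV Ctl had 2, 3 and 8 mice in these bands, T2CV SD 12, 1 and 4, 5xFAD/T2CV Ctl 8, 0 and 4, and 5xFAD/T2CV SD 4, 0 and 3. The groups thus differ in their bands, so a difference between groups may in part be one between bands. No sequencing batch or date is given in the sources used here.

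Groups were compared with edgeR 4.0.16 in R 4.3.3: filterByExpr over the 4 groups (minimum count 10, minimum total 15), TMM normalization, and the quasi-likelihood functions glmQLFit and glmQLFTest with group and labelled sex as terms. The filter kept 25106 genes and dropped 30381 features. TMM factors ran from 0.647 to 1.58, and the median prior degrees of freedom were 7.03. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and the threshold was 0.05. The comparisons were 5xFAD/T2CV Ctl against T2CV Ctl, SD against Ctl in each genotype, 5xFAD/T2CV SD against T2CV SD, the interaction of SD with genotype, female against male, and the interaction of sex with genotype in the Ctl mice. Levels are TMM-normalized CPM per mouse, given as mean ± SD, and fold changes are log2 ± standard error.

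Gene lists written before the data were examined were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, at the preset correlation of 0.01 and again with a correlation estimated from the data. There were 15 lists of responses: plaque-associated microglia, homeostatic microglia, complement, antigen presentation, interferon response, reactive astrocytes, lysosome, immediate early genes, endoplasmic reticulum chaperones, cytosolic heat shock, circadian clock, glucocorticoid response, cholesterol synthesis, synapse and mitochondrially encoded genes. The 14 lists of cell types covered myelinating oligodendrocytes, oligodendrocyte precursors, homeostatic astrocytes, interneurons, dentate granule cells, CA1 pyramidal cells, thalamic neurons, choroid plexus, ependymal cells, endothelial cells, pericytes, fibroblasts, red blood cells and peripheral leukocytes. Their p-values were adjusted over the lists of a comparison. Counts of list members past the threshold are also given adjusted over the list alone.

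The genes named in the text follow a rule fixed before the data were examined. In each comparison of groups it takes, among genes past the threshold with an average log2 CPM of at least 1, those with the 10 largest rises and the 10 largest falls, leaving out Xist and Y-linked genes. From each list it takes up to 4 tested members with the smallest p. App, Thy1, Trem2, Prnp, Cirbp and Rbm3 are given whatever their p. Some genes that the rule takes are not reported here. For sex and its interaction it takes the 6 autosomal genes with the smallest p, with Xist and Ddx3y as a check of the labels. List members printed as examples were picked from those the rule names. Exceptions were chosen after their values were seen: Cyp3a11, Dhrs7c, Tsix, 0610005C13Rik and Gm4017, which complete short sets of called genes, and Neurod6, Prl, Gh and Ttr, which describe single libraries or serve as a covariate.

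The lists, the rule, the comparisons, the redrawn groupings and a first set of alternatives were chosen before the data were examined. These alternatives were DESeq2 size factors in place of TMM, the Wald test of DESeq2 1.42.0, no filter on low counts, each library as its own replicate, the band of the title number as a covariate or 1 band alone, 2 surrogate variables from sva 3.50.0, no sex covariate, and a fit to only the 2 groups compared. Chosen after seeing the data were leaving out mice in doubt, edgeR's earlier quasi-likelihood fit, leaving out each mouse in turn, and the tests of technical explanations. The 19 libraries in doubt fell under 1 or more of these grounds: fewer than 10 M counts (1 library), a Thy1 level on the other side of 300 CPM from its genotype label (6), Xist and Y-linked genes against the sex label (6), or a median correlation with the other libraries under 0.95 (10). They were 6 of T2CV Ctl, 6 of T2CV SD, 5 of 5xFAD/T2CV Ctl and 2 of 5xFAD/T2CV SD, each from a mouse of its own. Leaving out mice by Thy1 selects on a gene that the 5xFAD transgenes carry in part, so values of Thy1 after that step are not independent evidence. The step also removes the 3 libraries of 5xFAD/T2CV Ctl with low Trem2, so microglial values after it are not independent of the choice either.

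For each comparison the groups were redrawn at random within the same samples, 60 groupings with the real one included. The test was also run on simulated counts in which 200 of 25106 genes were changed. Except for sex and its interaction, the 28 genes of plaque-associated microglia were raised too, and calls among them were not counted as false. It recovered 40% of 2-fold and 93% of 4-fold changes in 5xFAD/T2CV Ctl against T2CV Ctl, 47% and 93% in T2CV SD against Ctl, 27% and 70% in 5xFAD/T2CV SD against Ctl, and 31% and 74% in 5xFAD/T2CV SD against T2CV SD. The interaction recovered 8% and 49%, sex 72% and 98%, and the interaction of sex with genotype 1% and 27%. False calls made up 6.99%, 8.5%, 8.49%, 10.3%, 18.6%, 12.4% and 12.5% of calls in that order, above the nominal 5%. Each share came from 1 simulated draw, so its own spread is not known. The simulation drew negative binomial counts at the trended dispersion and the real depths. In it all labels were right and no library stood apart in its genes. Its rates therefore need not hold for the real counts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for tables and plots.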

Results

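Hippocampal gene expression was measured at 4 months in T2CV and 5xFAD/T2CV mice, each in a control condition (Ctl) and under SD, with 13 and 17 T2CV mice and 12 and 7 5xFAD/T2CV mice respectively. Median depth was 47.2 M (mega-counts) of assigned reads per library, and 25106 genes were tested. Gene positions are on GRCm38.

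Thy1 was set against the genotype labels, because the 5xFAD transgenes use parts of the Thy1 gene whose reads can align to the mouse gene. Thy1 lay between 95.4 and 193.6 CPM in 31 of the 33 T2CV libraries and between 513.3 and 1804 CPM in 15 of the 19 5xFAD/T2CV libraries. The libraries labelled T2CV SD replicate 4 and T2CV Ctl replicate 11 had 772.4 and 814.5 CPM. Those labelled 5xFAD/T2CV Ctl replicates 2, 7 and 8 and 5xFAD/T2CV SD replicate 6 had 107.8 to 257.3 CPM. The microglial gene Cst7 was 0 to 0.265 CPM in those 4 libraries and 0.289 to 15.2 CPM in the 15. In the T2CV libraries it did not follow Thy1, with 0.687 and 1.76 CPM in the 2 and 0 to 2.11 CPM in the 31. All 6 libraries against the genotype label were among 13 with a Trem2 level of at most 4.43 CPM, against at least 9.11 CPM in the other 39.

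Xist, expressed from the inactive X chromosome, and 4 Y-linked genes were set against the sex labels. Xist was 11.7 to 156.0 CPM in 20 libraries labelled female and at most 0.954 CPM in 26 labelled male. In 3 libraries labelled female it was 0.476 to 3.36 CPM with 148.5 to 336.2 CPM of the Y-linked genes. In 3 labelled male it was 78.5 to 129.0 CPM with at most 0.210 CPM of the Y-linked genes. These 6 were the libraries labelled T2CV SD replicates 10 and 11, T2CV Ctl replicates 6, 9 and 10, and 5xFAD/T2CV SD replicate 6. The labels were kept as given, and each comparison was repeated without these mice.

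**Figure D1:**
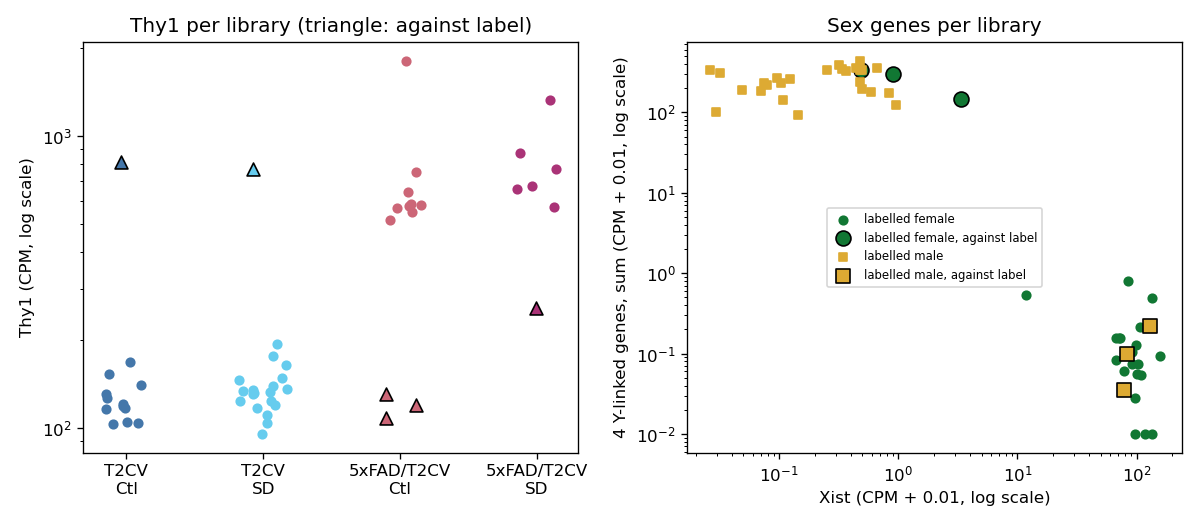
Left, Thy1 (CPM, log axis) in each library by group, with triangles for 6 libraries on the other side of 300 CPM from their genotype label. Right, Xist against the sum of 4 Y-linked genes (CPM + 0.01, log axes) by sex label, with outlined points for 6 libraries against their label.

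The first question was what 5xFAD changes in the hippocampus without SD. Cst7, an inhibitor of lysosomal proteases made by microglia around amyloid plaques, was 6.03-fold higher in 5xFAD/T2CV Ctl (4.21 ± 4.28 CPM, SD, n = 12) than in T2CV Ctl (0.776 ± 0.675 CPM, n = 13). Its log2 fold change was 2.59 ± 0.51 (adjusted p = 0.0373), and 7 of the 12 mice lay above the highest T2CV Ctl mouse. Stard4, which carries cholesterol between membranes, rose 1.69-fold, from 13.1 ± 3.25 to 22.1 ± 4.69 CPM (log2 0.76 ± 0.14, adjusted p = 0.0356), with 12 of 12 mice above the T2CV Ctl median. Cst7 (ENSMUSG00000068129) lies on chromosome 2 from 150570415 to 150578944, and Stard4 (ENSMUSG00000024378) on chromosome 18 from 33199355 to 33213862. Clec7a, a microglial receptor for glucans, gave 2.18 ± 0.46 without passing the threshold (adjusted p = 0.0901). Ccl6, a chemokine, gave 1.48 ± 0.42 (adjusted p = 0.301), and Spp1, which encodes osteopontin, 1.85 ± 0.53 (adjusted p = 0.329).

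**Figure D2:**
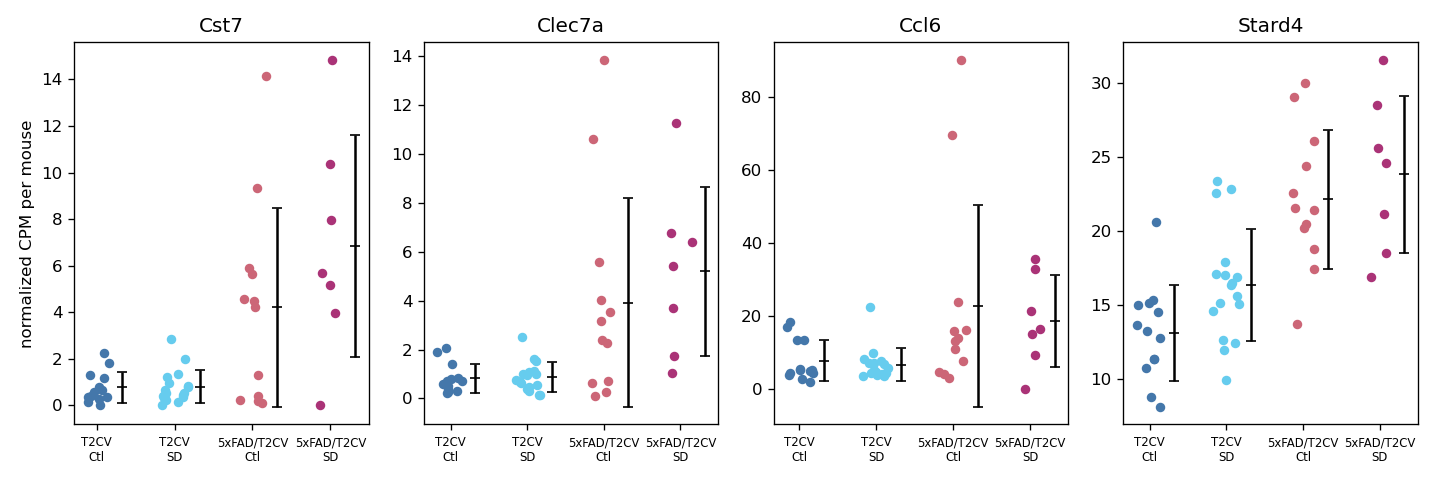
Normalized CPM per mouse of Cst7, Clec7a, Ccl6 and Stard4 in the 4 groups, with black bars for mean ± SD. Mean Cst7 was 0.776 and 0.805 CPM in T2CV Ctl and SD, and 4.21 and 6.85 CPM in 5xFAD/T2CV Ctl and SD.

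Among the 28 genes of plaque-associated microglia, 23 had positive fold changes in the Ctl mice (median log2 0.62), 1 rose and none fell, and 11 rose when adjusted over the list alone. The list passed camera at the preset correlation (adjusted p = 8.6e-06), with an adjusted p = 0.481 with an estimated correlation. The 14 genes of homeostatic microglia had a median of -0.0049 (adjusted p = 0.261). All 17 genes of cholesterol synthesis had positive fold changes (median 0.34, adjusted p = 2.2e-05, and 0.481 with an estimated correlation), and 1 rose when adjusted over the list alone. Insig1, which holds back sterol synthesis, gave 0.77 ± 0.22 (adjusted p = 0.315), with 11 of 12 mice above the T2CV Ctl median. The 10 choroid plexus genes moved with the group (median 0.92, adjusted p = 2.7e-04, and 0.643 with an estimated correlation). None of the other 26 lists passed: complement had a median of 0.39, interferon response 0.25, reactive astrocytes 0.29, lysosome 0.15, antigen presentation 0.07 and the circadian clock 0.14 (adjusted p from 0.107 to 0.275). Among the others, immediate early genes had a median of -0.04, synapse -0.05, endoplasmic reticulum chaperones -0.07 and glucocorticoid response -0.14. Thalamic neuron genes were at 0.34 (6 of 6 positive, adjusted p = 0.276) and dentate granule cell genes at -0.20 (1 of 6 positive, 0.200). Cytosolic heat shock and mitochondrially encoded genes had medians of 0.01 and 0.02, while their tests pointed down (adjusted p = 0.292 and 0.275).

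Of the key genes, Thy1 gave 1.76 ± 0.39 (adjusted p = 0.104). App, the amyloid precursor gene, gave 0.28 ± 0.12 and the microglial receptor gene Trem2 0.73 ± 0.53. Prnp was at -0.08 ± 0.14, and the cold-inducible genes Cirbp and Rbm3 at 0.02 ± 0.19 and -0.11 ± 0.23. In all, 4 genes rose and none fell, against 1463 at an unadjusted p under 0.05. The remaining 2 were chosen after their values were seen: Cyp3a11 (4.95 ± 0.99) and Dhrs7c (3.82 ± 0.77), a liver and a muscle enzyme gene. They had medians of 0 and 0.116 CPM in 5xFAD/T2CV Ctl and highest mice at 11.9 and 14.8 CPM. Over the alternatives Cst7 ranged from 2.52 to 3.52 and Stard4 from 0.63 to 0.92, and both calls ended in 7 of them. Both also ended when any 1 of T2CV Ctl replicates 2, 5, 6, 7, 9, 10 and 13 was left out, each of which gave 0 calls. Without all mice in doubt they were 3.52 (adjusted p = 2.6e-04) and 0.81 (5.9e-04), over a range of adjusted p from 1.2e-04 to 0.999. In that fit 4 lists also passed with an estimated correlation: plaque-associated microglia (median 0.84, adjusted p = 0.00455), cholesterol synthesis (0.39, 0.00455), lysosome (0.30, 0.0120) and complement (0.69, 0.0256). It leaves out 5xFAD/T2CV Ctl replicates 2, 7 and 8, with Trem2 of at most 2.16 CPM and Cst7 of at most 0.265 CPM. The gain in Cst7 and microglial lists is thus not independent of which mice were left out. Without mice in doubt on grounds other than Thy1, which keeps these 3, 0 lists passed with an estimated correlation.

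The second question was what SD changes in T2CV mice. Title numbers under 300 belonged to 12 of the 17 SD mice and 2 of the 13 Ctl mice, so SD and band were partly confounded. No gene passed the threshold in edgeR, and 767 had an unadjusted p under 0.05; DESeq2 also called 0. Npas2, a transcription factor of the circadian clock, was at 9.92 ± 3.01 CPM under SD (n = 17) and 6.91 ± 2.58 CPM in Ctl (n = 13), a log2 fold change of 0.51 ± 0.17 (adjusted p = 1.00), with 13 of 17 mice above the Ctl median. Nr1d1, a clock repressor, gave 0.36 ± 0.17. The chaperone genes of the endoplasmic reticulum pointed the other way: Hspa5 gave -0.30 ± 0.14, Creld2 -0.47 ± 0.20 and Manf -0.49 ± 0.24. The interferon-induced Bst2 gave -0.48 ± 0.24 and Gbp2 -0.70 ± 0.27, each below the Ctl median in 15 of 17 mice. Kl and F5, which the choroid plexus expresses, gave -0.77 ± 0.35 and -1.27 ± 0.58, and Slc17a6, a glutamate transporter gene of thalamic neurons, 1.08 ± 0.44 (-0.013 without the least correlated libraries). All of these had adjusted p of 1.00, as did the key genes: App 0.11 ± 0.11, Thy1 -0.23 ± 0.35, Trem2 0.11 ± 0.50, Prnp -0.08 ± 0.13, Cirbp 0.10 ± 0.18 and Rbm3 0.07 ± 0.21.

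At the preset correlation 9 of the lists passed in T2CV mice, and none of them with an estimated correlation (adjusted p from 0.273 to 0.504). Fold changes were negative for all 10 choroid plexus genes (median -1.03, adjusted p = 1.9e-08), for all but 1 of 14 endoplasmic reticulum chaperones (-0.19, 1.1e-04), all 12 antigen presentation genes (-0.30, 1.9e-04) and all but 1 of 18 interferon response genes (-0.25, 5.0e-04). Clock genes were positive in 15 of 19 (0.15, 0.00246) and thalamic neuron genes in 6 of 6 (0.61, 0.0487). Fibroblast genes were positive in 1 of 7 (-0.26, 0.0283) and ependymal genes in 0 of 6 (-0.41, 0.0476). The test of reactive astrocytes pointed down (0.0493), with 9 of 20 positive, a median of -0.06 and no member that fell. The choroid plexus list thus moved with the group, and without all mice in doubt its median was -0.64 (adjusted p = 0.0340, and 0.921 with an estimated correlation) while the other 8 no longer passed. In that fit 4 lists passed at the preset correlation, 3 of them upward and not among the 9, and 0 with an estimated correlation. Thalamic neuron genes then had a median of -0.11 (2 of 6 positive, adjusted p = 0.835). Slc17a6 was at 366.4 and 178.9 CPM in the libraries labelled T2CV SD replicates 12 and 14, both among the mice in doubt, and at most 65.6 CPM in the others of the group. Immediate early genes had a median of 0.07 with the test pointing down (adjusted p = 0.369), and cholesterol synthesis 0.13 (0.0665). Plaque-associated and homeostatic microglia were at -0.0021 and -0.12 (adjusted p = 0.549 and 0.0826).

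The same question in 5xFAD/T2CV mice gave 95 genes that rose and 0 that fell, with 2189 at an unadjusted p under 0.05. Most of these calls rested on 1 library: 86 of the 95 were highest in the one labelled 5xFAD/T2CV SD replicate 6, with 1.78 M counts, and without it 0 genes passed. Fzd8, a Wnt receptor gene (ENSMUSG00000036904, chromosome 18, 9212163 to 9218136), gave 5.67 ± 0.84 (adjusted p = 4.9e-05). It had 82.8 ± 214.9 CPM under SD (n = 7), with a median of 1.09 CPM, against 1.31 ± 0.603 CPM in Ctl (n = 12). Gm26461, Gm22567, Gm14029 and Gm43333, predicted genes whose assignment is uncertain where near-identical copies exist, gave 9.93, 8.59, 8.07 and 6.70 (adjusted p from 8.9e-07 to 1.3e-04). Gm15484 (4.09), Gm12328 (3.80), the muscle receptor gene Chrnb1 (3.90), the cilium gene Ccdc40 (3.56), the transcription factor gene Six5 (3.47) and the inhibitory vesicle transporter gene Slc32a1 (1.80 ± 0.42) also passed, with adjusted p up to 0.0260. The median log2 fold change of the 95 genes was 3.62, and 0.38 without that library.

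Stress and blood genes did not pass in that comparison: the chaperone gene Hspa1b gave 1.94 ± 0.54 (adjusted p = 0.111), the iron-binding Lcn2 2.02 ± 0.67 (0.264) and Ifitm3, an interferon-induced membrane protein gene, 0.91 ± 0.30 (0.239). The globin genes Hbb-bt and Hba-a2, near-identical copies of their neighbours, gave 2.41 ± 0.79 and 2.35 ± 0.79 (0.258 and 0.280). Red blood cell genes were positive in 5 of 5 (median 2.23), 4 rose when adjusted over the list alone, and the list passed at the preset correlation (adjusted p = 0.0292). In 5xFAD/T2CV SD, replicate 1 alone had Hba-a2 at 314.7 and Hbb-bt at 278.2 CPM, against at most 38.4 and 32.9 CPM in its other mice. Lysosome (-0.18) and myelinating oligodendrocyte genes (-0.27) had the same adjusted p of 0.0292, and all 3 lists had 0.877 with an estimated correlation. Plaque-associated microglia gave 0.19 (adjusted p = 0.426), interferon response 0.23 (0.426) and the circadian clock -0.17 (0.426). None of the key genes passed: App -0.02 ± 0.15, Thy1 0.43 ± 0.45, Trem2 0.08 ± 0.64, Prnp -0.20 ± 0.17, Cirbp -0.16 ± 0.23 and Rbm3 -0.11 ± 0.28, with adjusted p from 0.749 to 0.984.

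The third question was how the genotypes differ under SD. Cst7 was 11.1-fold higher in 5xFAD/T2CV SD (6.85 ± 4.78 CPM, SD, n = 7) than in T2CV SD (0.805 ± 0.724 CPM, n = 17), with a log2 fold change of 3.47 ± 0.53 (adjusted p = 5.9e-05), and 6 of 7 mice lay above the highest T2CV SD mouse. Clec7a rose 6.10-fold, to 5.19 ± 3.47 from 0.873 ± 0.600 CPM (2.61 ± 0.51, adjusted p = 0.00197), in 7 of 7 mice above the T2CV SD median. The chemokine genes Ccl3 and Ccl4, whose sequences are close to one another, gave 2.33 ± 0.50 and 2.28 ± 0.49 (0.00490 and 0.00595). The interferon-induced chemokine gene Cxcl10 gave 1.99 ± 0.42 (0.00490), and Fdps, an enzyme gene of sterol synthesis, 0.89 ± 0.21 (0.0187). The antiviral genes Bst2 (1.40 ± 0.29, 0.00349), Ifitm3 (1.30 ± 0.28, 0.00490) and Ifi27l2a (1.76 ± 0.43, 0.0208) rose, as did Timp1, a protease inhibitor gene of reactive astrocytes (1.74 ± 0.41, 0.0154). Without the library labelled 5xFAD/T2CV SD replicate 1, Bst2 was 1.07, Ifitm3 0.74 and Ifi27l2a 1.27, and these calls, with those of Ccl4 and Timp1, ended. Cst7 stayed past the threshold in all 23 alternatives, over adjusted p from 4.7e-06 to 0.0102.

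Of the 28 genes of plaque-associated microglia, 23 were positive (median 1.00), 8 rose, and 16 rose and 1 fell when adjusted over the list alone (adjusted p = 2.4e-04, and 0.393 with an estimated correlation). All 18 interferon response genes were positive (median 0.65), 3 rose, and 9 rose when adjusted over the list alone (5.4e-04, and 0.393 with an estimated correlation). Reactive astrocytes (0.30, 18 of 20 positive, 0.00459) and antigen presentation (0.47, 12 of 12, 0.00909) passed at the preset correlation, with 0.393 with an estimated correlation. Homeostatic astrocyte genes were negative in 8 of 8 (-0.30, 0.00675, and 0.393 with an estimated correlation). Lists of cells from outside the hippocampus moved too: choroid plexus (1.42, 3.0e-04), red blood cells (2.34, 0.00519) and peripheral leukocytes (1.97, 0.0189), with adjusted p from 0.393 to 0.394 with an estimated correlation. Complement (0.49, adjusted p = 0.102), cholesterol synthesis (0.10, 0.610), lysosome (0.01, 0.202) and homeostatic microglia (0.02, 0.542) did not pass, and lysosome and homeostatic microglia had medians above 0 with tests pointing down.

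Without all mice in doubt, plaque-associated microglia gave 1.05 (adjusted p = 0.00437 with an estimated correlation), interferon response 0.85 (0.0134), complement 0.65 (0.0134), cholesterol synthesis 0.29 (0.0107) and homeostatic microglia 0.23 (0.0264). Cst7 (3.46), Clec7a (2.60), Ccl3 (2.24), Ccl4 (2.11), Cxcl10 (2.02) and Fdps (1.00) passed in that fit. Bst2 (0.94), Ifitm3 (0.66), Ifi27l2a (1.19) and Timp1 (1.91) did not, with adjusted p from 0.0843 to 0.856.

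In total 362 genes rose and 0 fell between the genotypes under SD, with 3242 at an unadjusted p under 0.05. Of these, 208 were highest in the library labelled 5xFAD/T2CV SD replicate 6 and 140 in replicate 1. Without replicate 6 there were 113 calls and without replicate 1 there were 138. Without replicates 3, 5 and 4 there were 1055, 806 and 731, of which 74, 11 and 7 fell. Without all mice in doubt there were 35, of which 19 were among the 362. The largest rises were those of the library of low depth: Gm26461 10.81, Gm22567 9.50, Gm14029 7.74, Gm43333 7.16, Fzd8 5.85, Six5 3.94, Chrnb1 3.89, Gm15484 3.85, Gm12328 3.65 and Gm5566 3.63 (adjusted p from 2.2e-07 to 0.00166). Slc32a1 gave 1.70 ± 0.40 (0.0152). The neutrophil gene S100a8 (3.02 ± 0.65, 0.00531), the cilium gene Dynlrb2 (2.01 ± 0.49, 0.0187) and Hbb-bt (2.66 ± 0.70, 0.0349) were at 0.51, 0.59 and 0.96 without replicate 1, no longer past the threshold. Thy1 gave 2.41 ± 0.41 (3.6e-04). App gave 0.15 ± 0.14, Trem2 0.70 ± 0.60, Prnp -0.21 ± 0.16, Cirbp -0.24 ± 0.23 and Rbm3 -0.30 ± 0.28, with adjusted p from 0.612 to 0.691.

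**Figure D3:**
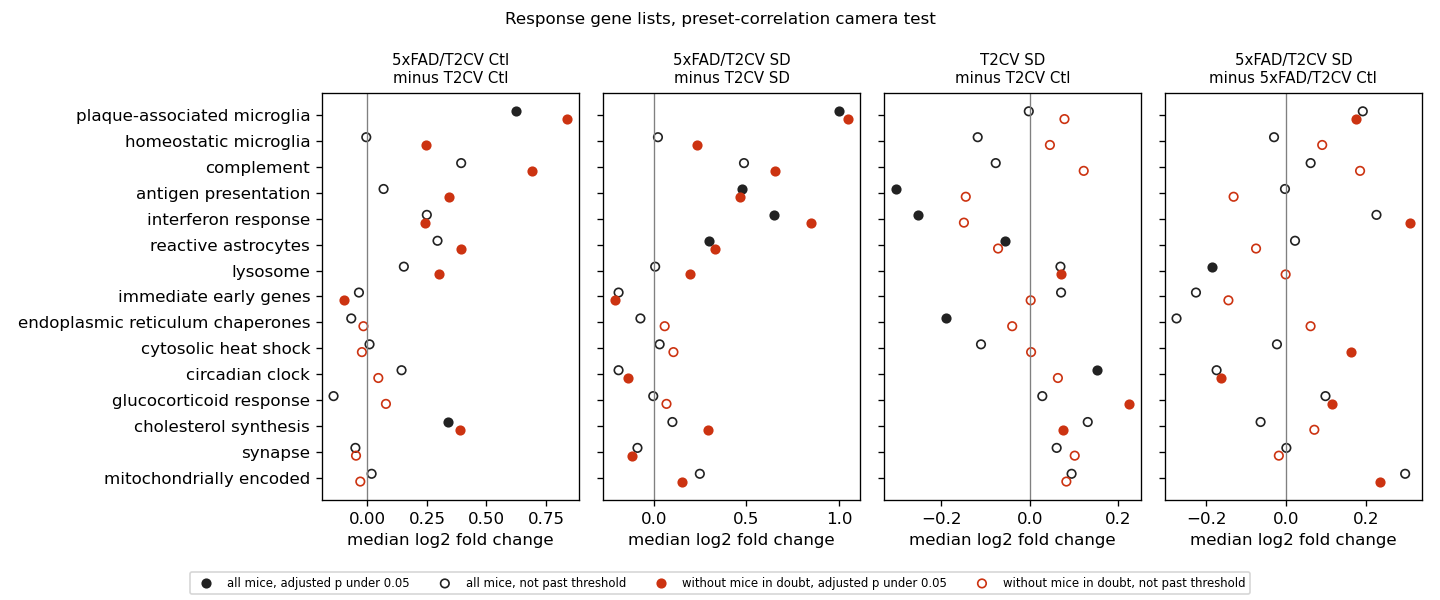
Median log2 fold change of the 15 response lists in 4 comparisons, black for all mice and red without mice in doubt; filled points have adjusted p under 0.05 at the preset correlation. Plaque-associated microglia had medians of 0.62 and 1.00 between the genotypes in Ctl and under SD, and 0.84 and 1.05 without mice in doubt.

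Whether SD acted differently in the genotypes was tested as an interaction. Npas2 and Nr1d1, which turn with the day, gave -0.82 ± 0.29 and -0.65 ± 0.27 (adjusted p = 0.671 and 0.788), and the 19 clock genes had a median of -0.26 (adjusted p = 0.0434, and 0.643 with an estimated correlation). Interferon response genes gave 0.49, lysosome -0.24 and myelinating oligodendrocytes -0.31 (0.0208 each). Homeostatic astrocytes gave -0.28 (0.0420), red blood cells 2.15 (0.0434) and dentate granule cells 0.55 (0.0435), all with 0.643 with an estimated correlation. The globin genes Hba-a2 and Hbb-bt were far above the rest of 5xFAD/T2CV SD in replicate 1 alone. Plaque-associated microglia did not pass (0.17, adjusted p = 0.237). At the gene level 3 rose and 0 fell, with 1419 at an unadjusted p under 0.05: Gm14029 (8.32 ± 1.55), Gm43333 (6.37 ± 1.25) and Fzd8 (5.72 ± 1.10), with adjusted p of 0.0461, 0.0481 and 0.0461. Leaving out any 1 of 37 of the 49 mice, 5xFAD/T2CV SD replicate 6 among them, gave 0 calls, as did the title-number band as a covariate. Without replicate 6 the 3 genes fell to 1.08, 0.32 and 0.47, so their size rested on that library. App was at -0.13 ± 0.19, Thy1 0.65 ± 0.57, Trem2 -0.03 ± 0.82, Prnp -0.13 ± 0.21, Cirbp -0.26 ± 0.29 and Rbm3 -0.19 ± 0.36.

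Female and male mice, as labelled, differed in 9 genes, 7 higher and 2 lower in females, of which 7 were autosomal; 2743 had an unadjusted p under 0.05. DESeq2 called 157 genes, 0 higher and 157 lower in females, with 0 of the 9 among them, since it gave none of the 9 an adjusted p. Ccr6, a chemokine receptor gene of lymphocytes, gave 3.80 ± 0.62 (adjusted p = 9.7e-04), at mean levels of at most 0.330 CPM in any group. The predicted genes Gm35021 (2.68 ± 0.44), Gm12454 (1.58 ± 0.29) and Gm49163 (1.77 ± 0.36) and the histone gene Hist1h2al (3.56 ± 0.71), which has near-identical copies, were higher in females. Gm45420 was lower (-1.62 ± 0.34). The remaining 3 were chosen after their values were seen: Tsix, which overlaps Xist, gave 1.59 ± 0.31, 0610005C13Rik 0.92 ± 0.20, and the Y-linked Gm4017, which lies within Ddx3y, -2.29 ± 0.41. Xist itself gave 3.92 ± 0.95 (adjusted p = 0.147) and Ddx3y -3.49 ± 0.93 (0.199). Without the 6 mice whose sex genes went against the label these were 8.15 and -11.18, which is not independent of how those mice were picked. All 6 autosomal genes of the rule lost the call in at least 2 of 19 alternatives.

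Sex by genotype in the Ctl mice gave 0 genes in edgeR, with 850 at an unadjusted p under 0.05 and 1 called by DESeq2. The smallest p among autosomal genes belonged to 9830132P13Rik (-6.21), Gm37234 (-5.10), 4930417O13Rik (-5.51), Set (-2.98), the muscle ligase gene Trim63 (-5.02) and Lrrc17 (-3.51), with adjusted p from 0.371 to 0.493. Set, a histone chaperone gene with many pseudogene copies, had 1409 ± 3674 CPM in 5xFAD/T2CV Ctl (n = 12) and a highest mouse at 13080 CPM.

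Across the 25106 genes, the fold changes of SD in T2CV and in 5xFAD/T2CV mice correlated with Pearson's r = 0.026 and Spearman's rho = 0.031. The fold changes of 5xFAD in Ctl and under SD correlated with r = 0.197 and rho = 0.244. Over 14559 genes with an average log2 CPM of at least 1 the values were 0.075 and 0.085 for SD, and 0.331 and 0.355 for 5xFAD. These are correlations across genes, which are not independent replicates, and both use the same 49 mice. Without all mice in doubt Pearson's r was 0.105 for SD and 0.063 for 5xFAD, so the order of the 2 turned.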

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

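The redrawn groupings were fixed in advance, and the tests of low depth, of mixed samples, of choroid plexus RNA and of the share of microglia were chosen only after the results were seen.

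Only the group 5xFAD/T2CV SD was small enough for a Dixon test, and in it 23 of 38 measures had 1 mouse far from the other 6. Chance alone gives this in about 1 in 20 groups, but that rate does not apply to genes named for their large rises, which replicate 6 produced, so their number is no evidence of its own. The mouse labelled replicate 6 stood apart in total counts (1.78 M) and in its median correlation with the other libraries (0.634). Its predicted genes were far above the rest, with Gm43333 at 22960 CPM, Gm26461 at 3547, Gm14029 at 924.8, Gm22567 at 751.6, Gm12328 at 415.1, Gm5566 at 243.4 and Gm15484 at 210.0 CPM. Fzd8 was at 570.2, Ccdc40 at 290.7, Chrnb1 at 276.5, Six5 at 187.1, Slc32a1 at 112.3, Hspa1b at 49.2 and Lcn2 at 28.6 CPM. App (255.1 CPM) was below the others. The mouse labelled replicate 1 stood apart with 16.03% of counts from mitochondrial genes, 10.2% from the top gene mt-Rnr2, Hba-a2 at 314.7, Hbb-bt at 278.2, Ifitm3 at 188.2 and Dynlrb2 at 55.0 CPM.

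The interaction test called some genes and lists with all mice: Gm14029 (8.32), Gm43333 (6.37) and Fzd8 (5.72), and the lists of red blood cells (2.15), dentate granule cells (0.55), interferon response (0.49), lysosome (-0.24), circadian clock (-0.26), homeostatic astrocytes (-0.28) and myelinating oligodendrocytes (-0.31). The 3 genes lost the call without any 1 of 37 of the 49 mice, replicate 6 among them, and with the title-number band as a covariate. No list passed with an estimated correlation. Of 60 groupings, 27 gave as many genes as the real 3 and the highest other gave 2628, and 11 gave as many lists as the real 7 with a highest other of 10, so chance could not be excluded. A grouping that calls several times the real count points to a structure of the samples, whose source was not tested.

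The 95 genes higher in 5xFAD/T2CV SD than in 5xFAD/T2CV Ctl were weighed first. An effect of SD in these mice as a group failed its test for the 95 genes. Without the library of 1.78 M counts their median log2 fold change was 0.3812, with quartiles of -0.02 and 0.73, against 3.62 with it. Since 86 of the 95 were highest in that library, a fall was built in, so the test cannot decide on a smaller effect. It says nothing about other genes. That library alone as the source predicts no calls without it, and 0 remained. With 86 of the 95 highest in it, their loss was built in here too, so this test cannot decide. The count was also 0 in some fits that kept the library: with only the 2 groups compared, and with only the highest band of title numbers. Why a library of low depth holds so much of a few predicted genes was not tested. Of 60 groupings, 22 gave as many calls as the real 95 and the highest other gave 2653, so chance could not be excluded.

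The libraries whose Thy1 or sex genes went against the labels were weighed next. Of the 5 with over 10 M counts against the genotype label, 0 had Thy1 between the ranges of the labels. For those labelled 5xFAD/T2CV Ctl replicates 2, 7 and 8 this argues against an even mixture of the genotypes. It cannot decide for the 2 T2CV libraries at 772.4 and 814.5 CPM. The 5xFAD/T2CV range of 513.3 to 1804 CPM is wide enough to hold a mixture. The library of low depth, left out of this test, lay between the ranges of the labels at 257.3 CPM. The 5 such libraries against the sex label were picked by whether Xist or the Y-linked genes were higher, which a mixed sample could also meet. Of them, 0 had both above the range of the sex that lacks them. The library of low depth, left out here too, had both above: Xist at 3.36 CPM against at most 0.954 CPM in males that fit their label. Its Y-linked genes were at 148.5 CPM against at most 0.784 CPM in females that fit theirs. Whether the labels themselves are wrong was not tested, since the genes that picked these libraries cannot also test it. Cst7 in the 2 T2CV libraries with high Thy1 (0.687 and 1.76 CPM) lay within the ranges of both labels and decides nothing.

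The third pattern was the plaque-associated microglia list in 5xFAD/T2CV Ctl against T2CV Ctl. RNA from the choroid plexus was argued against as its whole source: with the level of the choroid plexus gene Ttr as a covariate the list's median was 0.661, against 0.62 without it, while that of choroid plexus genes went from 0.92 to 0.28. A larger share of microglia at unchanged levels per cell was argued against as the whole source with all mice. Homeostatic microglia genes had a median of -0.004929 with an SD of 0.27 between members. More microglia that each hold less of these genes could give the same value, so the test cannot decide on that. Without mice in doubt the median of homeostatic genes was 0.24 beside 0.84 for the list, so a part of the change may come from more microglia. The mice left out include the 3 of 5xFAD/T2CV Ctl with low Trem2, so these 2 medians are not independent of that choice. A change of state within microglia, with or without more of them, is the hypothesis left open, found and tested on the same data.

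The redrawn groupings gave these results for the other counts. In 5xFAD/T2CV Ctl against T2CV Ctl, 20 of 60 gave at least the real 4 genes (highest other 204) and 37 the real 3 lists (highest other 10). In T2CV SD against Ctl, 10 gave the real 9 lists (highest other 16). In 5xFAD/T2CV SD against Ctl, 44 gave the real 3 lists (highest other 12). In 5xFAD/T2CV SD against T2CV SD, 3 gave at least the real 362 genes (highest other 694) and 14 the real 8 lists (highest other 13). For sex, 20 gave at least the real 9 genes (highest other 2483). Chance could not be excluded for any of these counts. The real count was 0 genes for T2CV SD against Ctl (highest other 20) and for sex by genotype (highest other 266), so that all 60 of 60 groupings gave as many by construction and nothing follows from it.

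For 3 of 4 single lists fewer than 5% of groupings gave as large a result, unadjusted over the 4 lists and on a scale of -log10 p at the preset correlation. With an estimated correlation none of the 3 passed (adjusted p = 0.481, 0.481 and 0.393). Cholesterol synthesis in 5xFAD/T2CV Ctl against T2CV Ctl reached 5.83 and the highest other grouping 4.07, so that 1 of 60, the real one, was as large. Plaque-associated microglia in that comparison reached 6.53, and 1 redrawn grouping exceeded it (7.29), so that 2 of 60 were as large. Interferon response in 5xFAD/T2CV SD against T2CV SD reached 4.26, again with 2 of 60 as large and a higher value in a redrawn grouping (5.38). Plaque-associated microglia under SD reached 5.08 in 3 of 60 (highest other 8.89), and there chance could not be excluded.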

How the results depend on the processing

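Under SD, the microglial gene Cst7 was past the threshold in all 23 alternatives, from 3.22 to 3.83 on the log2 scale, and Clec7a in 22 of 23. In the Ctl mice, Cst7 and Stard4 kept their direction in the alternatives run, and each lost its call in 7 of them. No call of that comparison was left when any 1 of 7 T2CV Ctl mice was omitted, named below. Over the genes named in the text and all their alternatives, 2339 values could be compared with an adjusted p. Of these, 1847 kept direction and side of the threshold, 309 were no longer past it, 27 were newly past it and 156 changed direction. Where DESeq2 gave no adjusted p, the value was left out: this held for 1 of the 4 genes called in 5xFAD/T2CV Ctl against T2CV Ctl, 83 of 95 in 5xFAD/T2CV SD against Ctl, 168 of 362 in 5xFAD/T2CV SD against T2CV SD, 3 of 3 in the interaction and 9 of 9 for sex. In every case below where no cause is named, the cause was not tested.

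Counts of genes changed with the fit. In 5xFAD/T2CV Ctl against T2CV Ctl, the 4 calls became 0 with no filter on low counts, with only the 2 groups compared, with only title numbers under 300, with edgeR's earlier quasi-likelihood fit, without mice whose sex genes went against the label, and without mice in doubt on grounds other than Thy1. They became 31 with the band of the title number as a covariate (3 shared), 27 with only title numbers of 900 and over (1 shared) and 17 without mice whose Thy1 went against the label (3 shared). In T2CV SD against Ctl the count was 0 in all alternatives except the fit with no sex covariate, which gave 4.

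The 95 calls of 5xFAD/T2CV SD against Ctl became 157 with no filter, 143 with no sex covariate, 839 with DESeq2 (12 shared), 1166 with the earlier fit and 5 with 2 surrogate variables. They became 0 with only the 2 groups compared, in either band of title numbers alone, and in each of the 6 ways of leaving out mice in doubt, all of which remove replicate 6 by construction. The 362 calls of 5xFAD/T2CV SD against T2CV SD became 1535 with DESeq2, 1699 with the earlier fit, 24 with only the 2 groups compared and 1 with only title numbers under 300. Leaving out mice gave 113 (lowest depth), 88 (Thy1 against the label), 64 (sex genes against the label), 30 (least correlated libraries), 15 (grounds other than Thy1) and 35 (all in doubt).

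The 3 calls of the interaction became 1 with no filter, 5 with each library as its own replicate, 0 with the band as a covariate, 1 with surrogate variables, 83 with DESeq2, 16 with no sex covariate and 360 with the earlier fit. They became 0 without the library of lowest depth, Thy1-discordant, sex-discordant or least correlated mice, and 1 without mice in doubt on other grounds or on any. For sex, the 9 calls became 5 with the band, 157 with DESeq2 (0 higher and 157 lower in females, 0 shared), 1 with the earlier fit, 4 without Thy1-discordant, 21 without sex-discordant mice and 16 without mice in doubt on grounds other than Thy1. Sex by genotype went from 0 to 1 with DESeq2.

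Counts of gene lists past the threshold became 0 with an estimated correlation in all 5 comparisons. In 5xFAD/T2CV Ctl against T2CV Ctl, the 3 lists became 5 without the library of lowest depth, 8 without Thy1-discordant mice, 13 without the least correlated, 14 on grounds other than Thy1 and 12 without all in doubt. In T2CV SD against Ctl, the 9 lists became 5 with the band, 7 without the lowest depth, 7 without Thy1-discordant, 3 without sex-discordant mice, 6 without the least correlated, 3 on grounds other than Thy1 and 4 without all in doubt. In 5xFAD/T2CV SD against Ctl, the 3 lists became 9, 6, 9, 14, 14 and 9 without the lowest depth, Thy1-discordant, sex-discordant, least correlated, otherwise doubted and all doubted mice. In 5xFAD/T2CV SD against T2CV SD the 8 lists became 13, 13, 13, 16, 14 and 15 in that order. The 7 lists of the interaction became 10 without the least correlated, 8 without the lowest depth, 6 without Thy1-discordant, 5 without sex-discordant mice, 3 with the band, 3 on grounds other than Thy1 and 2 without all in doubt.

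Across genes, the correlation of SD fold changes between genotypes went from 0.026 to 0.135 with the band as a covariate and 0.160 without the least correlated libraries. Its sign turned to -0.026 without the library of lowest depth and -0.072 without sex-discordant mice. It was 0.0096 without Thy1-discordant mice, 0.114 on grounds other than Thy1 and 0.105 without all in doubt. That of 5xFAD fold changes between Ctl and SD went from 0.197 to 0.333 with the band, 0.165 without the library of lowest depth, 0.203 without Thy1-discordant and 0.122 without sex-discordant mice, 0.060 without the least correlated, 0.037 on grounds other than Thy1 and 0.063 without all in doubt.

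Leaving out each mouse in turn, the count in 5xFAD/T2CV Ctl against T2CV Ctl ran from 0 to 8. It was 0 without T2CV Ctl replicates 2, 5, 6, 7, 9, 10 or 13, 1 without T2CV Ctl replicates 1, 8 or 12 or 5xFAD/T2CV Ctl replicate 1, and 2 without T2CV Ctl replicate 3 or 5xFAD/T2CV Ctl replicates 5 or 12. It was 7 without T2CV Ctl replicate 4 or 5xFAD/T2CV Ctl replicate 2, and 8 without 5xFAD/T2CV Ctl replicate 8. In T2CV SD against Ctl it was 0 throughout. For 5xFAD/T2CV SD against Ctl it ran from 0 (without 5xFAD/T2CV SD replicate 6) to 259 (replicate 5), with 190, 206, 237 and 248 without replicates 7, 2, 4 and 3. For 5xFAD/T2CV SD against T2CV SD it ran from 113 (replicate 6) to 1055 (replicate 3), with 138, 806 and 731 without replicates 1, 5 and 4 and 566 without T2CV SD replicate 13. The interaction ran from 0, without any of 37 mice, to 17 (5xFAD/T2CV SD replicate 3), with 7 without replicate 1, 10 without replicate 7 and 11 without replicates 2, 4 or 5. Sex ran from 5 (5xFAD/T2CV Ctl replicate 2 or T2CV SD replicate 15) to 21 (T2CV SD replicate 10), with 17 without T2CV Ctl replicate 9 and 18 without 5xFAD/T2CV SD replicate 1.

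Changes of direction were those of genes high in replicate 6 and of others not past the threshold with all mice. In the settings that leave it out, which are the 6 ways of leaving out mice in doubt and title numbers under 300, the construction shows the cause for the genes high in it. Without the library of lowest depth, which is replicate 6, 5xFAD/T2CV SD against Ctl gave Gm22567 -0.30, Chrnb1 -0.52, Gm12328 -0.059, Ccdc40 -0.28 and Six5 -0.30, and 5xFAD/T2CV SD against T2CV SD gave Chrnb1 -0.44 and Gm12328 -0.14. In that fit App was 0.11 and Rbm3 0.010 in the first comparison, and Trem2 0.12 and Prnp 0.00087 in the interaction. Without each of the other mice of 5xFAD/T2CV SD in turn, the first 5 reached at most 9.36, 4.25, 4.12, 3.88 and 3.84, and the last 2 4.29 and 4.01. Without each of the 7 in turn, App ran from -0.092 to 0.11, Trem2 from -0.13 to 0.28, Cirbp from -0.35 to 0.017 and Rbm3 from -0.26 to 0.097 in the first comparison. In the interaction Trem2 ran from -0.26 to 0.16, Rbm3 from -0.33 to 0.043 and Prnp from -0.23 to 0.00087. Without Thy1-discordant mice, Gm22567 was -0.52, Chrnb1 -0.39, Gm12328 -0.027, Ccdc40 -0.17 and Six5 -0.40 in the first comparison, Chrnb1 -0.38 and Gm12328 -0.13 in the second, and Thy1 -0.0068 in the interaction. App was 0.051 and Trem2 -0.16 in the first, Thy1 0.11 in T2CV SD against Ctl and Rbm3 0.056 in 5xFAD/T2CV Ctl against T2CV Ctl. Without sex-discordant mice these were Gm22567 -0.33, Chrnb1 -0.53, Gm12328 -0.071, Ccdc40 -0.29 and Six5 -0.30, and Chrnb1 -0.48 and Gm12328 -0.15. App was 0.096 and Rbm3 0.0038 in the first, Cirbp -0.061 in 5xFAD/T2CV Ctl against T2CV Ctl, and Trem2 0.23, Prnp 0.011 and Rbm3 0.0031 in the interaction.

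Without the least correlated libraries, 5xFAD/T2CV SD against Ctl gave Gm26461 -0.13, Gm43333 -0.82, Fzd8 -0.088, Chrnb1 -0.58, Ccdc40 -0.48, Six5 -0.78, Slc32a1 -0.17, Prnp 0.051, Rbm3 0.19, App 0.044 and Cirbp 0.046. 5xFAD/T2CV SD against T2CV SD gave Gm26461 -0.24, Gm14029 -0.48, Gm43333 -0.91, Six5 -0.11, Chrnb1 -0.45, Slc32a1 -0.22, Cirbp 0.12 and Rbm3 0.10. T2CV SD against Ctl gave Slc17a6 -0.013, Thy1 0.61 and Prnp 0.050, 5xFAD/T2CV Ctl against T2CV Ctl Rbm3 0.10, and the interaction Gm43333 -1.25, Trem2 0.46, Prnp 0.00069 and Rbm3 0.0017.

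Without mice in doubt on grounds other than Thy1, 5xFAD/T2CV SD against Ctl gave Gm26461 -0.13, Gm43333 -0.83, Fzd8 -0.10, Chrnb1 -0.57, Ccdc40 -0.47, Six5 -0.75, Slc32a1 -0.17, Prnp 0.050, Rbm3 0.20, App 0.043 and Cirbp 0.037. 5xFAD/T2CV SD against T2CV SD gave Gm26461 -0.26, Gm14029 -0.58, Gm43333 -1.01, Six5 -0.14, Chrnb1 -0.47, Slc32a1 -0.25, Cirbp 0.065 and Rbm3 0.086. T2CV SD against Ctl gave Slc17a6 -0.0036, Thy1 0.64 and Prnp 0.070, 5xFAD/T2CV Ctl against T2CV Ctl Rbm3 0.070, and the interaction Gm43333 -1.31, Trem2 0.53 and Rbm3 0.017.

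Without all mice in doubt, 5xFAD/T2CV SD against Ctl gave Gm14029 -0.13, Gm43333 -0.85, Fzd8 -0.12, Chrnb1 -0.47, Ccdc40 -0.36, Six5 -0.90, Slc32a1 -0.18, Prnp 0.026 and Rbm3 0.11. 5xFAD/T2CV SD against T2CV SD gave Gm26461 -0.35, Gm14029 -0.64, Gm43333 -0.96, Six5 -0.090, Chrnb1 -0.43, Slc32a1 -0.25, Cirbp 0.036 and Rbm3 0.068. 5xFAD/T2CV Ctl against T2CV Ctl gave Rbm3 0.15, T2CV SD against Ctl Thy1 0.27 and Prnp 0.057, and the interaction Gm14029 -0.061 and Gm43333 -1.30.

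With 2 surrogate variables, a fit that keeps replicate 6 and where the cause was not tested, Gm22567 was -0.25, Chrnb1 -0.32, Ccdc40 -0.24, Six5 -0.16 and App 0.11 in 5xFAD/T2CV SD against Ctl, Chrnb1 -0.31 and Gm12328 -0.17 in 5xFAD/T2CV SD against T2CV SD, Thy1 0.16 in T2CV SD against Ctl and App 0.0084 in the interaction. App in 5xFAD/T2CV SD against Ctl was 0.033 with DESeq2 and also with its size factors. Trem2 in the interaction was 0.011 with those size factors and 0.077 with each library as its own replicate. With only title numbers under 300, which leave out replicate 6, 5xFAD/T2CV SD against Ctl gave Chrnb1 -0.50, Gm12328 -0.16, Ccdc40 -0.27, Six5 -0.17 and App 0.15, 5xFAD/T2CV SD against T2CV SD Chrnb1 -0.33 and Gm12328 -0.26, and 5xFAD/T2CV Ctl against T2CV Ctl Prnp 0.090 and Rbm3 0.70. With only title numbers of 900 and over, Rbm3 was -0.24 and Cirbp -0.0096 in T2CV SD against Ctl, and Trem2 -0.71 and Thy1 -0.0043 in 5xFAD/T2CV SD against Ctl.

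No paired analysis was possible because no label pairs a mouse of one group with a mouse of another. Depth limited 1 library, the one labelled 5xFAD/T2CV SD replicate 6, and the other 51 had at least 29.3 M counts. With all mice, 2-fold changes were recovered in at most 72% of simulated genes in any comparison, so a gene that did not pass is not shown to be unchanged.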

Other observations

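No list of neuronal or vascular genes passed the threshold between the genotypes in the Ctl mice. In 5xFAD/T2CV Ctl against T2CV Ctl, CA1 pyramidal cell genes had a median log2 fold change of -0.13 (2 of 6 positive, adjusted p = 0.218), dentate granule cell genes -0.20 (0.200) and interneuron genes 0.05 with a test pointing down (0.593). Oligodendrocyte precursors were at -0.03 (0.276), endothelial cells at -0.09 (0.194) and pericytes at -0.10 (0.128). Without all mice in doubt, pericyte genes were lower in 5xFAD/T2CV SD than in T2CV SD (median -0.37, 0 of 6 positive, adjusted p = 0.00361, and 0.0203 with an estimated correlation). With all mice that median was -0.16 (adjusted p = 0.199), and chance was not tested for this list. Genes encoded in mitochondria were positive in 13 of 13 in T2CV SD against Ctl (median 0.09, adjusted p = 0.667) and in 11 of 13 in 5xFAD/T2CV SD against Ctl (0.30, 0.380).

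Trem2, which encodes a lipid-sensing receptor of microglia, took low and high levels in every group. In 13 libraries it was 1.49 to 4.43 CPM and in the other 39 it was 9.11 to 92.2 CPM, so that the largest step between neighbouring values was 2.06-fold. The low libraries numbered 3 of 13 in T2CV Ctl, 5 of 20 in T2CV SD, 3 of 12 in 5xFAD/T2CV Ctl and 2 of 7 in 5xFAD/T2CV SD. All 6 libraries whose Thy1 went against the genotype label were among the 13: those labelled 5xFAD/T2CV Ctl replicates 2, 7 and 8, which were the 3 low ones of that group, 5xFAD/T2CV SD replicate 6, T2CV SD replicate 4 and T2CV Ctl replicate 11. The other 7 fitted their genotype label. The labels used here give no reason for the low levels, and no samples were compared by them. Leaving out mice by Thy1 did, however, remove all 3 low libraries of 5xFAD/T2CV Ctl.

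Single libraries held genes of neighbouring tissue or little of a hippocampal gene. The library labelled T2CV SD replicate 12 had 366.4 CPM of Slc17a6 and 5.12 CPM of Neurod6, a gene of hippocampal pyramidal cells. Neurod6 was at 117 to 617 CPM in all other libraries. Replicate 12 was kept in the fit of all mice. In replicate 14 of that group Slc17a6 was at 178.9 CPM and Neurod6 at 297.2 CPM. The library labelled 5xFAD/T2CV Ctl replicate 11 had 6807 CPM of Prl and 6356 CPM of Gh, both pituitary hormone genes. The 3 pairs of T2CV SD libraries that share a title number (146, 164 and 965) correlated at 0.972, 0.974 and 0.965. Their counts differed with a chi-square per degree of freedom of 101.8, 107.1 and 200.6, against a median of 135.7, 106.9 and 89.6 for pairs with the other libraries of the group. The first pair was closer than that median, the second about at it and the third farther apart, and some other pairs were closer than each (lowest 52.3, 32.4 and 36.6). Trem2 was at 24.4 and 2.76 CPM in the first pair, 2.52 and 1.58 in the second and 3.45 and 56.8 in the third.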
